A study of Oryza sativa with 2 samples.

How the data were processed

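Small RNA was sequenced from superior and from inferior spikelets of rice, with 1 library each. Per the labels' protocols, total RNA was extracted with Trizol and treated with DNase, RNA of 18 to 30 nt was cut from a denaturing gel, adapters were ligated, and 15 cycles of PCR came before Illumina sequencing. Each deposited file lists the length, the read count and the sequence of every distinct read, and the count is a raw number of reads that the authors had not normalized. Per the note the authors deposited with the files, reads of low quality had been removed and reads of 18 to 30 nt kept. The adapter trimmer, and any aligner and genome build, are not given in the sources used here. Every sequence stood on 1 line, and the length column equalled the length of the sequence in every line. Reads were counted without molecular identifiers, so the 15 cycles of PCR could have copied some molecules more than others.

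Groups came from the tissue labels. Library totals were the sums of all counts, 10034728 reads in the superior and 9283494 in the inferior library, and RPM, reads per 1000000 reads, were taken over these totals. Before the data were examined, a list of 103 mature microRNA sequences in 56 families and 16 opposite-strand sequences was written from general knowledge, together with the family lists, the calling rule, the rule for named families and the alternative settings. The listed sequences were not checked against a microRNA database or a genome, neither of which was used here. A name therefore means that a read equals the listed sequence, and a family never read may be present as another form. A family's count is the sum of exact matches to its listed sequences.

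For each family the ratio of RPM, inferior over superior, was given with the exact conditional binomial 95% interval for 2 counts. A family was called lower or higher when the ratio reached 2-fold and the interval excluded 1, among families with at least 10 reads over both libraries. Shares of reads have exact (Clopper-Pearson) binomial 95% intervals. Medians weighed under Other observations have 95% intervals from 10000 resamplings of the families or sequences. No p-value was computed, since each group has 1 library. The text names every family with at least 100 reads and the 5 most abundant of each library, gives families of 10 to 99 reads as counts unless a described list holds them, and names the 3 unlisted sequences with the highest and the 3 with the lowest ratio among those with at least 1000 reads. miR394 and single members of families were named outside this rule after their values were seen.

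The family lists were development, auxin, nutrient and metal, small RNA pathway, and rice or grass lineage, and a family can be in more than 1 list. A list's median log2 ratio, with 0.5 added to each count, was set among 10000 random lists of the same size. These were drawn from the 100 unlisted 20 to 22 nt sequences nearest in mean abundance to each family, and the percentile describes these libraries only. The planned search for rRNA, tRNA and organelle sequence in a reference was not run, because no genome was used here. It was replaced by exact matches to 11 rRNA and tRNA sequences written from general knowledge after the most abundant sequences had been seen. Mitochondrial sequence was not analysed here.

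The alternatives were reads sharing the first 18 nt of a mature sequence at 19 to 24 nt, edgeR TMM factors and DESeq2 size factors over the listed families, 20 to 22 nt reads or reads other than 24 nt as the total, other read minimums, a 1.5-fold rule, single sequences in place of families, several sets of reads left out of the size classes, and the opposite-strand ratio over fewer families. TMM and DESeq2 factors assume that most listed families do not differ, and RPM assume that the total of 18 to 30 nt RNA is the same in both samples. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. edgeR and DESeq2 gave scaling factors only.

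The ratio, its interval and the call were tested on simulated data drawn from the real abundances and depths. For the 41 families, over 20 simulations, 99% of families with a true 4-fold increase, 98.5% with a true ratio of 0.25 and 98.1% of unchanged families got the right call, and 95.2% of intervals held the true ratio. For 402 sequences with at least 1000 reads, 100% got the right call in each class, and 95.6% of intervals held the true ratio. The simulation has counting error only and no variation between plants. It held no true ratio near the 2-fold cut, so these percentages do not describe calls of families close to that cut. Its counts were drawn at the same totals used for scaling, so it does not test the choice of scale.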

Results

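Small RNA reads of 18 to 30 nt were counted in 2 libraries from developing grains of the japonica rice cultivar Xinfeng 2, both collected 18 days after fertilization. One library came from superior spikelets, which flower early on the upper branches of the panicle and fill quickly. The other came from inferior spikelets, which flower later on the lower branches and fill slowly. The superior library held 10034728 reads of 4581492 distinct sequences, and the inferior library held 9283494 reads of 3028914 distinct sequences. With 1 library per group, no difference has a replicate check, and no p-value is given. The 95% intervals of ratios and shares, and the floors, cover counting error only, and PCR reads without molecular identifiers are not independent molecules. Intervals of medians under Other observations cover the spread between families or sequences instead. A difference between the libraries is therefore a difference between these 2 samples, and it was not tested as a difference between spikelet types. A count of 0 allows up to 3 reads, which is 0.299 reads per 1000000 reads (RPM) in the superior library and 0.323 RPM in the inferior library. No reference genome was used here, so sequences carry no coordinates, and they are written as DNA.

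The first comparison asked how the size classes of small RNA differed between the spikelet types. In plants, 21 nt reads hold most microRNAs, and 24 nt reads hold mainly the siRNAs that direct DNA methylation. The 24 nt class made up 50.7% of reads in superior spikelets (exact binomial 95% interval 50.66 to 50.72) and 65.3% in inferior spikelets (65.30 to 65.36), 1.29 times as large a share in inferior spikelets. The 21 nt class went the other way, with 19.5% of reads in superior spikelets (19.52 to 19.56) and 8.11% in inferior spikelets (8.09 to 8.13), a 2.41-fold larger share in superior spikelets (2.40 to 2.42). The 22 nt class held 7.34% and 6.50%, and the 23 nt class held 7.69% and 7.89%. Among distinct sequences the 24 and 21 nt classes hardly differed, while the 25 nt class held 2.59% and 3.94%. Distinct 24 nt sequences were 58.0% in superior and 56.0% in inferior spikelets, which turned the direction of the 24 nt difference, and 21 nt sequences were 9.16% and 8.81%. The difference lay in reads per distinct sequence. A 24 nt sequence was read 1.92 times on average in superior and 3.57 times in inferior spikelets, and a 21 nt sequence 4.67 and 2.82 times.

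**Figure D1:**
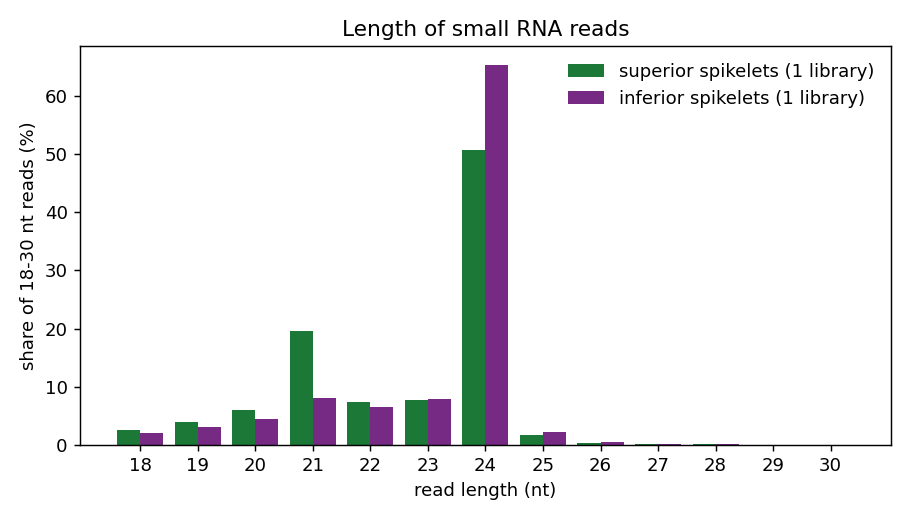
Share of reads (percent, vertical axis) at each read length (nt, horizontal axis), with 1 bar per library. The 24 nt bar is 50.7% in the superior and 65.3% in the inferior library, and the 21 nt bar is 19.5% and 8.11%; no error bars are drawn, since each group has 1 library.

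The inferior library also held fewer different sequences. The ratio of distinct sequences was 0.661, and it was 0.704 after the superior library was thinned to the depth of the inferior one. Thinning adjusts depth only, so uneven PCR copying was not separated from a difference between the tissues. Sequences read once were 80.7% of the distinct sequences in superior and 74.7% in inferior spikelets. The 10 most abundant sequences took 10.2% of reads in the superior library and 2.70% in the inferior library. As signs of RNA breakdown and of green tissue, listed cytosolic rRNA fragments were 0.884% of reads in superior and 1.197% in inferior spikelets, and listed chloroplast tRNA fragments were 0.0311% and 0.188%. The rRNA fragments all matched 5.8S or 5S rRNA, so other rRNA is not covered. The chloroplast difference came from tRNA-His alone (2796 and 17295 reads), and the other 4 chloroplast tRNAs that were read had ratios of inferior over superior from 0.458 to 0.937.

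The main comparison asked which microRNA families differed between the spikelet types, and most were lower in inferior spikelets. All listed microRNAs together were 5.77% of superior reads (5.76 to 5.79) and 1.47% of inferior reads (1.46 to 1.48), a 3.92-fold larger share in superior spikelets (3.90 to 3.95). Without miR168 and miR156 the difference was 1.92-fold, and over 20 to 22 nt reads it was 2.29-fold. The list held 56 families, of which 45 were read and 41 had at least 10 reads. Among these 41, 25 were at least 2-fold lower in inferior spikelets with an interval that excluded 1, 1 was at least 2-fold higher, and 15 were neither. The median family was 2.72-fold lower in inferior spikelets, or −1.44 on the log2 scale. This count depends on the scale. Relative to 20 to 22 nt reads alone, every family shifts by 0.79 (log2), giving 14 lower and 7 higher, although 10 of the 41 families, 4 of these 14 among them, are 24 nt sequences outside that total. Relative to reads other than 24 nt the shift is 0.51, giving 19 lower and 3 higher, and the same 10 families lie outside that total. Under edgeR TMM factors the shift is 1.32 with 11 lower and 11 higher, and under DESeq2 size factors it is 1.44 with 8 lower and 12 higher. Both sets of factors were estimated from these same 41 families. DESeq2 factors thereby put the median family at equality by construction, and TMM left a median of −0.12. Higher or lower on these 2 scales is therefore relative to the typical listed family and is no check of the direction in RPM. All these shifts are upward, so only ratios below 1 could turn. The families called lower on all these scales were miR164, miR168, miR397, miR408, miR528, miR820, miR1861 and miR1873. This list rests on exact matches. The most read form of miR820, of 24 nt, was less than 2-fold lower under TMM and DESeq2 factors (log2 −0.94 and −0.82). The most read form of miR167, of 22 nt, stayed more than 2-fold lower there (−2.21 and −2.09), although miR167 is not in the list.

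**Figure D2:**
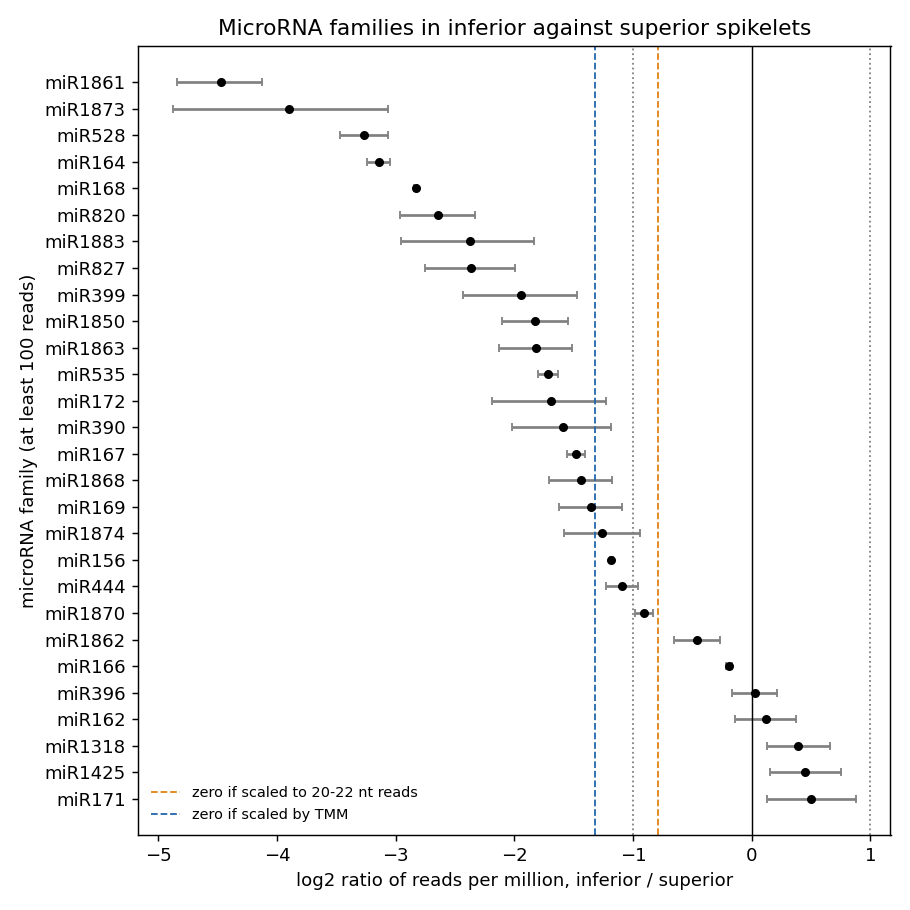
Log2 ratio of RPM, inferior over superior (horizontal axis), for the 28 families with at least 100 reads (vertical axis); points are the ratios, bars their 95% counting intervals, and dotted lines mark 2-fold. Of these families 20 lie at least 2-fold below equality and 0 at least 2-fold above it; dashed lines show where equality would lie relative to 20 to 22 nt reads and under TMM, where families to the right of the line turn to higher in inferior spikelets.

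Families of the small RNA pathway list include the most abundant microRNA of the superior library. Of its 4 families, 3 were lower in inferior spikelets and 1 was neither, and under TMM factors 2 were lower and 1 was higher. miR168 (TCGCTTGGTGCAGATCGGGAC), which targets the AGO1 gene of the silencing complex, had 374240 reads in superior and 48678 in inferior spikelets, a 7.11-fold difference (7.05 to 7.18). It made up 64.6% of all listed microRNA reads in the superior library and 35.7% in the inferior library. miR820, which targets the DNA methyltransferase gene DRM2, was 6.24-fold lower in inferior spikelets (5.03 to 7.82), from 648 and 96 reads. miR390, which triggers trans-acting siRNAs from TAS3 precursors, was 3.02-fold lower (2.28 to 4.05). miR162, which targets the microRNA-processing enzyme gene DCL1, had 253 and 254 reads, a ratio of inferior over superior of 1.09 (0.908 to 1.30), and was 2-fold higher or more under TMM and DESeq2 factors. The list's median log2 ratio was −2.11, at percentile 33.2 among random lists of unlisted 20 to 22 nt sequences of like abundance, whose own median was −0.86. Under TMM factors the list's median was −0.79.

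The development list had 11 families with enough reads, of which 7 were lower in inferior spikelets, 0 were higher and 4 were neither. Under TMM factors only miR164 was lower and 4 were higher, and relative to 20 to 22 nt reads only miR164 was lower and 2 were higher. miR164, which targets NAC transcription factors, was 8.84-fold lower in inferior spikelets (8.26 to 9.46), from 8943 and 936 reads. The difference came from 1 member, miR164e (TGGAGAAGCAGGGCACGTGAG), with 8319 and 182 reads, 42.3-fold lower (36.5 to 49.2). miR164e stayed lower on every scale tried, while miR164a,b,f had 598 and 741 reads, a ratio of inferior over superior of 1.34 (1.20 to 1.49). miR535 was 3.29-fold lower (3.11 to 3.47), and miR172, which targets AP2-like transcription factors, was 3.24-fold lower (2.34 to 4.56). Within miR172, miR172a,d had 136 and 12 reads and stayed lower on every scale tried, and miR172b had 32 and 36, a ratio of 1.22 with an interval that holds 1 (0.734 to 2.02). miR167, which targets auxin response factors, was 2.79-fold lower (2.65 to 2.93), and 7.42-fold lower (7.20 to 7.66) with 3′ variants, from 35674 and 4446 reads. miR169, which targets NF-YA transcription factors, was 2.56-fold lower (2.13 to 3.08) but turned under DESeq2 factors to a log2 ratio of 0.089. Its members also diverged, with 324 and 49 reads of miR169b,c, which stayed lower on every scale tried, and 75 and 105 reads of miR169a, a ratio of 1.51 (1.11 to 2.06).

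miR156, which targets SPL transcription factors, was the most abundant family of the inferior library, with 146092 reads in superior and 59469 in inferior spikelets. It was 2.27-fold lower in inferior spikelets (2.25 to 2.29), and turned to higher under TMM and DESeq2 factors (log2 0.13 and 0.26). miR444, which targets MADS-box genes, was 2.13-fold lower (1.95 to 2.34) and turned in the same way (0.23 and 0.35). miR166, the regulator of class III HD-ZIP genes, had 21878 and 17724 reads, and its ratio of inferior over superior was 0.876 (0.858 to 0.893). Its members diverged: miR166a-d,f (18391 and 12704 reads) had a ratio of 0.747 (0.730 to 0.764), which turned to a log2 ratio of 0.90 under TMM, while miR166k,l (1768 and 3088) had 1.89 (1.78 to 2.00), miR166g,h (1681 and 1881) had 1.21 (1.13 to 1.29) and miR166e (19 and 41) had 2.33 (1.32 to 4.25). miR396, which targets growth-regulating factors, had a ratio of 1.02 (0.893 to 1.16), and miR171, which targets GRAS transcription factors, had a ratio of 1.42 (1.09 to 1.84). These 3 families did not reach 2-fold in RPM and were higher in inferior spikelets under TMM and DESeq2 factors. The development median was −1.18 (percentile 26.97 of random lists with a median of −0.63), and it turned to 0.13 under TMM.

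In the auxin list, 3 of 5 families were lower in inferior spikelets and 2 were neither. The lower families were miR164, miR167 and miR390, given above. miR160, which targets auxin response factors, had 30 and 40 reads, and miR393, which targets the TIR1 and AFB auxin receptors, had 15 and 20; neither reached 2-fold in RPM, and both were higher in inferior spikelets relative to 20 to 22 nt reads and under TMM and DESeq2 factors. The median of the list was −1.48, at percentile 28.2 of random lists with a median of −0.46, and it was −0.16 under TMM.

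All 5 measured families of the nutrient and metal list were lower in inferior spikelets, with a median of −3.26 (percentile 26.4 of random lists with a median of −0.76). miR528, which targets ascorbate oxidase and other copper protein genes, was 9.60-fold lower (8.37 to 11.1), from 2346 and 226 reads. miR827, which targets SPX-domain protein genes, was 5.14-fold lower (3.98 to 6.73), and miR399, which targets the phosphate-homeostasis gene PHO2, was 3.84-fold lower (2.78 to 5.40). Of the laccase and plantacyanin regulators, miR397 had 51 reads in superior and 1 in inferior spikelets, 47.2-fold lower with an interval of 8.10 to 1899.7. miR408 had 27 and 1 reads, 24.98-fold lower with an interval of 4.12 to 1023. The list kept a median below 0 relative to 20 to 22 nt reads (−2.47) and under TMM (−1.94).

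Of 22 measured families of the rice and grass lineage list, 13 were lower in inferior spikelets, 0 were higher and 9 were neither. Under TMM factors 6 were lower and 4 higher, and relative to 20 to 22 nt reads 8 were lower and 3 higher. miR1861 (CGATCTTGAGGCAGGAACTGAG) was 22.2-fold lower (17.5 to 28.7), from 1682 and 70 reads, and miR1873 was 15.0-fold lower (8.37 to 29.4), from 194 and 12 reads. miR1883 was 5.19-fold lower (3.57 to 7.76), miR1850 was 3.54-fold lower (2.93 to 4.30) and miR1863 was 3.52-fold lower (2.86 to 4.37). miR1868 was 2.72-fold lower (2.27 to 3.27). miR1874 was 2.39-fold lower (1.92 to 2.99) and turned to log2 ratios of 0.061 under TMM and 0.18 under DESeq2 factors. The families miR1870, miR1862, miR1318 and miR1425 had ratios of inferior over superior of 0.534, 0.729, 1.31 and 1.37, and all 4 lay above 1 under TMM and DESeq2 factors. The listed miR1318 and miR1432 sequences are offset copies of nearly the same stretch. The median was −1.35, at percentile 5.24 of random lists with a median of −0.19, and it was −0.028 under TMM. The random lists hold 20 to 22 nt sequences only, while 10 of the 22 families are 24 nt sequences, so this percentile compares unlike lengths.

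The family at least 2-fold higher in inferior spikelets was miR394, which targets an F-box protein gene, with 23 and 49 reads and a ratio of 2.30 (1.38 to 3.96). The 13 families with 10 to 99 reads included 5 lower and this 1 higher. By exact matches, the most abundant families after miR168 and miR156 were miR166, miR164 and miR167 in superior spikelets (2180.2, 891 and 593 RPM). In inferior spikelets miR156 and miR168 (6406 and 5243.5 RPM) were followed by miR166, miR1870 and miR167 (1909, 235 and 213). With 3′ variants, miR167 (35674 reads) stood above miR166 (24968) and miR820 (23585) above miR164 (9032) in superior spikelets. Another 11 families were never read as listed, among them miR395 and miR398.

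The opposite strands of microRNA precursors, which are usually degraded, were compared with their mature strands in 14 families. They had 427 reads in superior and 391 in inferior spikelets, or 0.0761 and 0.301 reads per 100 mature reads, a 3.96-fold higher ratio in inferior spikelets (3.44 to 4.55). The pooled ratio depends on which families enter it: it was 2.18 (1.89 to 2.52) without miR168, which holds most mature reads, and 5.34 (4.64 to 6.14) over the 9 families whose listed opposite strand was read. In the other 5 the listed opposite sequence had 0 reads and could be wrong as written, although their mature reads count in the pooled ratio. Of the 8 families with at least 10 opposite reads, 6 had more opposite reads per mature read in inferior spikelets and 2 had fewer, with intervals that overlapped between the libraries for miR393 and miR408, both among the 6. Per 100 mature reads, superior and inferior spikelets had 90 and 20 for miR160, 6.97 and 0.218 for miR396, 0.229 and 0.773 for miR166, 3.56 and 8.20 for miR167, 0.00828 and 0.0308 for miR168, 9.43 and 36.7 for miR171, and 26.7 and 35 for miR393. The listed opposite strand of miR408 outnumbered its mature strand in both libraries. The opposite strand of miR166 had 50 and 137 reads, 2.96-fold more by RPM in inferior spikelets (2.13 to 4.18), and that of miR171 had 10 and 51 reads, 5.51-fold more (2.77 to 12.2). The opposite strands of miR396 (34 and 1 reads), miR408 (58 and 10 reads) and miR160 (27 and 8 reads) were lower in inferior spikelets. Their log2 ratios stayed below 0 on every scale tried, but not always by 2-fold. For miR160 the log2 ratio was −0.85 relative to 20 to 22 nt reads, −0.32 under TMM and −0.20 under DESeq2 factors. For miR408 it was −0.98 under DESeq2 factors. The opposite strand of miR168 had 31 and 15 reads, a ratio of 0.523 (0.262 to 0.998), and turned under TMM and DESeq2 factors (log2 0.38 and 0.51).

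The last comparison covered abundant sequences outside the microRNA list, 389 with at least 1000 reads over both libraries. Of these, 25 matched listed rRNA or tRNA and 12 overlapped listed microRNAs. Unlisted rRNA or tRNA among the others was not searched for. In inferior spikelets 102 of the 389 were at least 2-fold lower, 119 were neither, and the rest were at least 2-fold higher. Length separated them. Of 190 sequences of 24 nt, 138 were higher and 28 lower, with a median 5.53-fold higher in inferior spikelets. Of 76 sequences of 21 nt, 9 were higher and 39 lower, with a median 2.05-fold lower, which turned to a log2 ratio of 0.29 under TMM. The most extreme lower sequences were TGCAAGTGATGTAGCGCCCC (1096 and 1 reads, 1014-fold, interval 182 to 40085), AGGGACGCAGCGGAAGAGCAA (1361 and 3 reads, 419.7-fold, interval 143 to 2038) and GATGTAGACGGTGCCCATCCA (1107 and 3 reads, 341-fold, interval 117 to 1658). The most extreme higher sequences were AGGAAGAACGCCTGATACGCCGAT (44 and 981 reads, 24.1-fold, interval 17.8 to 33.4), AAATGAAGTAGAGCTGCACATGAC (68 and 1185 reads, 18.8-fold, interval 14.7 to 24.4) and AAGAGAAATGAATAAGATGGACGA (87 and 1091 reads, 13.6-fold, interval 10.9 to 17.1).

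**Figure D3:**
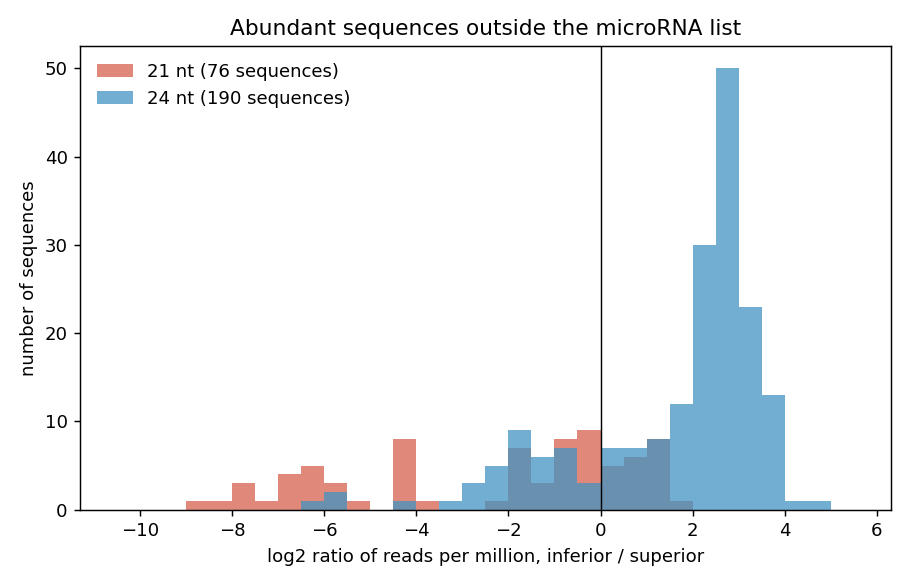
Number of sequences (vertical axis) by log2 ratio of RPM, inferior over superior (horizontal axis), for unlisted sequences with at least 1000 reads, 76 of 21 nt and 190 of 24 nt. The 24 nt sequences lie mostly to the right of equality (median 2.47), and the 21 nt sequences have a median of −1.03 and a tail to the left; under TMM every value would move right by 1.32.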

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

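The rRNA and tRNA sequences behind the values here were listed after the most abundant sequences had been seen, and no explanation of these values was tested.

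Fragments of rRNA and tRNA lie outside the microRNA comparison and stood above the 3 reads that a count of 0 allows in both libraries, with no control library to set them against. Cytosolic rRNA fragments had 88733 reads in superior and 111111 in inferior spikelets, 1.35 times as many by RPM in inferior spikelets (1.34 to 1.37). All of them matched 5.8S or 5S rRNA, so other rRNA is not covered by these counts. Nuclear tRNA fragments had 182918 and 83417 reads, 2.03-fold fewer by RPM in inferior spikelets (2.01 to 2.05), and nearly all came from tRNA-Ala (181893 and 82643 reads). Chloroplast tRNA fragments had 3123 and 17462 reads, 6.04-fold more by RPM in inferior spikelets (5.82 to 6.28). This came from tRNA-His, with 2796 and 17295 reads, 6.69-fold more (6.42 to 6.96). The other chloroplast tRNAs that were read, tRNA-Glu, tRNA-Arg, tRNA-Asp and tRNA-fMet, had ratios of inferior over superior from 0.458 to 0.937, so the chloroplast tRNAs did not move together.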

How the results depend on the processing

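Leaving out the listed rRNA and tRNA reads, leaving out listed and 1000-read sequences, the 20 to 22 nt total for family lists, reads other than 24 nt as the total, and the choice of families for the opposite-strand ratio were chosen after the data were seen. Intervals of large counts are so narrow that small moves count as moved. The cause of the moves was not tested, except that each scaling shifts every family by 1 factor. DESeq2 factors put the median listed family at equality by construction, and TMM factors put it near equality. For 25 families lower and 1 higher, the counts were 11 lower and 11 higher under TMM, 8 and 12 under DESeq2 factors, 14 and 7 relative to 20 to 22 nt reads, and 19 and 3 relative to reads other than 24 nt. The number higher was 2 with 3′ variants, 2 for single sequences and 0 with a minimum of 100 reads. The number lower stayed between 20 and 30 with 3′ variants, other minimums, a 1.5-fold rule, single sequences or no rRNA and tRNA. Of the 28 families with at least 100 reads, all 28 kept their call with 3′ variants and without rRNA and tRNA, 21 kept it relative to reads other than 24 nt, 16 relative to 20 to 22 nt reads, 10 under TMM and 8 under DESeq2 factors. Log2 ratios of lower families that turned were those of miR156 (0.13 under TMM, 0.26 under DESeq2), miR1874 (0.061, 0.18), miR444 (0.23, 0.35) and miR169 (0.089 under DESeq2). Of families under 2-fold, miR166 (1.13, 1.251), miR1870 (0.41, 0.54) and miR1862 (0.86, 0.99) turned under TMM and DESeq2, and miR166 (0.60) and miR1862 (0.34) relative to 20 to 22 nt reads (0.32 and 0.051 relative to reads other than 24 nt). With 3′ variants miR167 had a log2 ratio of −2.89.

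The ratio of the total microRNA share, 0.255, was 0.246 with 3′ variants, 0.521 without the most abundant family of each library and 0.437 over 20 to 22 nt reads. The 24 nt share ratio, 1.29, was 0.966 over distinct sequences (turned), 1.18 without the 10 most abundant sequences, 1.45 without sequences read once, 1.28 without rRNA and tRNA and 1.16 without listed and 1000-read sequences. The 21 nt ratio, 0.415, was 0.962, 0.514, 0.303, 0.399 and 0.543 in the same order. The ratio of distinct sequences was 0.704 after thinning. List medians under TMM were 0.13 for development (turned), −0.16 for auxin, −1.94 for nutrient and metal, −0.79 for small RNA pathway and −0.028 for grass lineage. Relative to 20 to 22 nt reads they were −0.39, −0.69, −2.47, −1.32 and −0.55. With 3′ variants the list medians and the opposite-strand ratio (4.26) stayed within their intervals. That ratio was 2.18 without miR168 and 5.34 over families with opposite-strand reads only. Depth limits families under 100 reads, such as miR397, whose interval runs from 8.10 to 1899.7. The planned removal of reference rRNA, tRNA and organelle matches was not run. No paired analysis was possible because each group has 1 library.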

Other observations

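Among forms that differ from the listed sequences in length or sequence, chosen after their values were seen, the gap between the libraries was often as wide as for the listed form. A 22 nt form of miR167, TGAAGCTGCCAGCATGATCTGA, had 28384 reads in superior and 2267 in inferior spikelets and was 11.6-fold lower in inferior spikelets (11.1 to 12.1). The 21 nt form lacking its last base had 425 and 347 reads. miR820 was read mostly as a 24 nt form, TCGGCCTCGTGGATGGACCAGGAG, with 15628 and 3022 reads, 4.78-fold lower (4.60 to 4.98). A 21 nt form of miR1861, GATCTTGAGGCAGGAACTGAG, had 4843 and 101 reads, 44.4-fold lower (36.4 to 54.6). A sequence variant of miR529 of the listed length, AGAAGAGAGAGAGTACAGCCT, had 8 and 45 reads, 6.08-fold higher in inferior spikelets (2.84 to 14.9), while the listed form had 5 and 2 reads. The 22 nt miR167, 24 nt miR820 and 21 nt miR1861 forms stayed lower on every scale tried. The miR820 form was less than 2-fold lower under TMM and DESeq2 factors (log2 −0.94 and −0.82). By first base, A opened 38.1% of 24 nt reads in superior and 42.3% in inferior spikelets, and T opened 46.1% and 38.6% of 21 nt reads.

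Of the tests below, those relative to 20 to 22 nt reads and to reads other than 24 nt, without rRNA and tRNA, on other 5′ ends, on overhangs, on neighbouring lengths and on 25 to 30 nt reads were chosen after the results were seen; for the removal of listed and 1000-read sequences, the setting was added after the data were seen but the bounds were written before its values.

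The lower level of most listed families in inferior spikelets could come from the larger 24 nt share, which leaves fewer reads for all other RNA. Relative to reads other than 24 nt the median log2 ratio of the 41 families was still −0.93 (−1.31 to −0.29, from resampling the families). However, 10 of the 41 are 24 nt sequences outside that total, of which 8 were lower over all reads. Scaling keeps the order of families, so the median of the 31 other families is the value of miR156, −0.68 on this scale. No interval was taken for it, so the test cannot decide for them. More rRNA and tRNA stays open, because only a few sequences were listed: these took a smaller share in the inferior library (2.28% against 2.74%), and leaving them out shifted every family by only −0.0067, to a median of −1.45. For the 31 families of 20 to 22 nt, the median relative to 20 to 22 nt reads was −0.39 (−0.92 to 0.77), so less 20 to 22 nt RNA of all kinds cannot be told apart from a lower level of the median family itself. Among them, 10 of 17 lower families stayed at least 2-fold lower, while 7 of the 31 were at least 2-fold higher. The 31 families therefore did not move by 1 common factor in these libraries. Because the 17 were picked for low ratios in these same data, their count cannot tell a decrease of these families from a spread around a change of all 20 to 22 nt RNA. A difference between spikelet types stays open and untested with 1 library each.

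A set of 27 unlisted 21 nt sequences, falling into 24 groups that share 16 nt or more, was at least 8-fold lower in inferior spikelets and took 3.57% of superior and 0.0588% of inferior reads. The most abundant, ATGAAGATGAATTGGAACATG, had 185686 and 2489 reads. Over-amplified single molecules are argued against, because forms of the same sequences with other 5′ ends were as low. Their median log2 ratio was −6.15 (−6.78 to −4.63, from resampling the sequences). For perfect duplexes cut with a 2 nt overhang, 11.3% (9.40 to 13.4) of 1020 complementary 21 nt reads of the superior library lay at that overhang. These partner reads were few beside the 358357 superior reads of the set. Opposite strands are usually degraded, so the partner reads that remain cannot decide on such duplexes. A source active in superior spikelets, or tissue present in one sample and not in the other, may explain the set, and neither was tested.

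The larger 24 nt and smaller 21 nt shares in inferior spikelets were weighed against a few abundant sequences and against the gel size selection. Without listed and 1000-read sequences the 24 nt ratio was 1.16 and the 21 nt ratio 0.543, so a few sequences are argued against as the whole cause, although both moved toward 1. A shifted gel size selection changes neighbouring lengths alike and is argued against for 21 nt, whose ratio was 0.517 times the geometric mean of its neighbours. For 24 nt, a shift toward longer RNA stays open, because the lengths went both ways: 25 to 26 nt reads had a larger share in inferior spikelets (ratio 1.32) and 18, 19 and 20 nt reads smaller ones (0.771, 0.754 and 0.728), as such a shift needs, but 27 to 30 nt reads, a small class, had a ratio of 0.8004 without rRNA and tRNA (0.785 to 0.816). A narrower size window and the spikelet type stay open too.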
